A study of Homo sapiens with 2 samples.

How the data were processed

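The series holds 1 pool of cells measured once. Per the series' design text, the pool combined pancreatic endoderm cells made from the human induced pluripotent stem cell line 585A1 and grafts recovered from NOD-SCID mice that had received such cells. Per the labels' protocols, pooled suspensions of 20000 cells were loaded on a BD Rhapsody system, which captures single cells with barcoded beads in microwells, and cDNA and hashtag libraries were amplified with TAS-Seq, a whole-transcriptome method for such beads. The fragmented cDNA went through 9 cycles of barcoding PCR before sequencing on an Illumina NovaSeq instrument. A hashtag is a barcoded antibody that marks all cells of 1 suspension before pooling. No label used here ties a hashtag to a condition, so each hashtag was kept as a separate sample of unknown condition. Class comparisons summed the cells of a class or of numbered clusters over the hashtags that held them, with list medians and values of some genes within single hashtags beside them, and no test was made between hashtags.

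The authors deposited a matrix of whole-number counts per gene and cell, with each cell named by its hashtag or as a doublet, and a second matrix of whole-number hashtag counts per barcode. Per the submitters' processing notes, FastQC 0.11.9, cutadapt 3.4, Bowtie2 2.4.2, R 4.1.2 and the genome build GRCh38 were used, without the role of each. The annotation release, the counting rule and whether molecular identifiers were collapsed are not given in the sources used here. Among nonzero entries of genes detected in 20 to 100 cells, 36.2% were above 1 and 2.11% above 10, as reads not collapsed by molecular identifier would give. The values are therefore called counts, and intervals computed from them cover counting error only and may be too narrow, because PCR copies are not independent molecules. How reads shared by near-identical or overlapping genes were counted is not given in the sources used here, so values of CTRB1 and CTRB2, CELA3A, CELA3B and AL590556.3, PRSS1, PRSS2 and PRSS3, AMY1A, AMY2A and AMY2B, REG1A, REG3A and REG3G, HBA1 and HBA2, HSPA1A and HSPA1B, PGA3, PGA4 and PGA5, and INS and INS-IGF2 are uncertain as to the member.

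The matrix held 8219 cells and 35084 named features. Features under the names "5" and "Metazoa", which name no single gene, held 0.0204% of all counts. Of the symbols, 32019 (91.3%) matched GENCODE release 29, which supplied the GRCh38 coordinates. Cells named by 1 hashtag numbered 7956. Cells were kept with at least 500 detected genes and under 20% of counts from the 37 mitochondrial genes, which left out 30 and 342 cells, partly the same ones. Scrublet was run through scanpy 1.11.5 on all cells with at least 200 genes and under 20% mitochondrial counts, including those the authors had named doublets. Of the 7613 single-hashtag cells that passed the filters, it called 103 (1.35%) at a score threshold of 0.15, which was set after the scores were seen. Its automatic threshold of 0.280 called 48 cells (0.63%). At 0.15 it called 37.2% of the cells the authors had named doublets. From the shares of the hashtags, 172 doublets within a hashtag were expected beside the 263 between hashtags, so some doublets remained among the 7510 kept cells.

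Counts were scaled to 10000 per cell and log-transformed. The 3000 most variable genes, chosen in 20 bins of mean expression after the 17 report lists had been left out, gave 30 principal components, a graph of 15 nearest neighbours and Leiden clusters at resolution 1.0 (igraph 0.11.9, leidenalg 0.10.2, scikit-learn 1.9.0, seed 1). A cluster took the name of the cell type marker list with the largest share of its markers counted, when at least 3 of its markers were detected in at least 25% of the cluster's cells and were at least 2-fold higher than in all other cells. The 17 lists covered acinar, ductal, pancreatic progenitor, endocrine progenitor, endocrine, mesenchymal, endothelial, immune, erythroid, neural or Schwann, hepatic, intestinal, gastric, pluripotent, smooth muscle or pericyte, mesothelial and proliferating cells. The proliferating list described a state and named no cluster. Leading genes were ranked by fold with 20 CPM added to both sides. A cluster was compared between hashtags under its class name only when its 10 leading genes held no more markers of another class than of its own, and otherwise by its number. It also needed at least 1 marker of its own there or at least 5 markers counted, which put clusters 13 and 27, with ductal markers, among the numbered ones. This last limit was set after the clusters had been seen. The detection, fold and count limits of this naming were set after the files had been read.

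For each comparison, counts were summed over the cells of each class and expressed as CPM, the count scaled by the total of the class to the usual common total. Log2 ratios used a prior of 0.5 counts in each class and carry the exact conditional binomial 95% interval of the ratio. Genes with at least 30 counts over both classes were measured. A gene is called higher or lower when it was measured, differed at least 2-fold, and had the same direction in each hashtag with at least 20 cells of both classes. This is a rule of size, not a test. Where a hashtag held few or no counts of a gene, its direction there can come from the prior and the totals alone. With 1 pooled library there are no replicates and cells are not replicates, so no p-values are given. Shares carry exact Clopper-Pearson 95% intervals, CPM values exact Poisson 95% intervals, and a share of 0 the limit that 3 counts would give. The median log2 ratio of each report list was ranked among 10000 random lists of the same size whose members were drawn from the 100 genes nearest in mean expression. Each member was drawn separately, while genes of a report list may vary together. The ranks give a position and are not a test, and small medians can reach extreme ranks. The rule for named genes took up to 3 members of each list with the largest ratio among those called, plus the 5 genes outside all lists with the largest ratio in each direction. Other genes are named where a count of few members asks for it, or as known members of a list, and these were chosen after their values were seen.

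The report lists covered further digestive enzymes, other acinar secretory and granule proteins, acinar transcription factors, ER and protein secretion, secretagogue receptors and exocytosis, Notch, WNT, Hippo and YAP, FGF and ERK, further ductal genes, further endocrine genes, fetal genes, DNA replication and mitosis, hypoxia and glycolysis, dissociation stress, MHC class I, and niche ligands. The lists, the rule for named genes, the cell filters and most of the other settings tried were fixed before the data were examined. So were the comparisons, except those that divided the clusters with pancreatic progenitor markers by hashtag. That division was chosen after the hashtags of the clusters had been seen. The other settings were other cell filters, resolutions, doublet handling and gene sets for the clustering, edgeR 4.0.16 TMM factors, CPM without dominant genes, thinning of each cell to 10000 counts, no count minimum, and leaving out each hashtag. Steps laid out for molecular identifiers were run on the counts as deposited. Scrublet's automatic threshold, the share of endocrine and endocrine progenitor clusters together, the endocrine share and comparison without cluster 18, and 4 other settings of the endocrine comparison were added after the data were seen. The comparison laid out as acinar-like against ductal-like cells was made against clusters 13 and 27 by number. Their ductal name rested on 3 markers each.

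The naming, ratio and list steps were tested on simulated data. For the acinar comparison, 28 of 58 genes changed 2-fold were called over 20290 genes, as were all 44 changed 3-fold, all 50 changed 4-fold and all 48 changed 8-fold, with calls at 0.338% of unchanged genes. For the endocrine comparison, 19 of 46 genes changed 2-fold were called over 25217 genes, as were all 50, 48 and 56 changed 3-fold, 4-fold and 8-fold, with calls at 0.324% of unchanged genes. A change of exactly 2-fold lies at the limit of the rule, so counting error alone puts such genes on either side of it. The acinar simulation drew cells of A952 and A953 only, without the 702 reference cells of A951. The simulated sums were Poisson counts, the model that the intervals assume, without PCR copies or differences between cells of a class. On them the intervals held the simulated ratio for 95.9% and 95.6% of the genes. Neither this share nor the rate of calls at unchanged genes can be carried over to the deposited counts. Of 100 random lists, 93 and 95 fell within the central range that should hold nearly all of them. All 300 simulated cells of each of 4 kinds were in clusters of the right name. The markers of each kind had been raised strongly, so weakly marked clusters were not tested. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, R 4.3.3 and matplotlib 3.10.9 were used.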

Results

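Single-cell transcriptomes were collected from 1 pool made with the human pluripotent stem cell line 585A1, an unedited line differentiated toward pancreas. The pool joined pancreatic endoderm cells, the embryonic stage from which acinar, ductal and endocrine cells arise, with grafts grown in immunodeficient mice. Cells were not filtered by species, so cells of the host may be among them. The series' title names human acinar development as its subject. The cDNA library held 8219 cells. Of these, 1313 carried hashtag A951 (15.98%, 95% interval 15.2 to 16.8), 2535 carried A952 (30.8%, 29.8 to 31.9) and 4108 carried A953 (50.0%, 48.9 to 51.1). The authors had named the other 263 cells (3.20%, 2.83 to 3.60) doublets. Total counts were 51681966, 82356225 and 136166180 for the 3 hashtags. Median counts per cell were 30730, 25234 and 25665, with single cells between 5783 and 267871, and the median numbers of detected genes were 4871, 4096 and 3946. The matching hashtag library held 56496674 reads over 804360 barcodes, 70.8% of them in cells of the matrix. In every cell named by a hashtag, that hashtag had the most reads, and the median share of the leading hashtag was 99.0%, 99.7% and 99.4% for A951, A952 and A953. It was 71.4% in the cells named doublets. There was 1 library and no replicate, so the intervals throughout cover counting error only. Which hashtag marked which suspension is not given in the sources used here.

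The 7510 kept cells formed 28 clusters, which differed widely between the hashtags. Acinar-like cells, named from CPA1, CTRB1, CTRB2, CLPS and other enzyme genes of the cells that make digestive juice, were all in cluster 7. They made up 143 of 2425 cells of A952 (5.90%, 4.99 to 6.91) and 271 of 3796 cells of A953 (7.14%, 6.34 to 8.00). In A951 there were 0 of 1289 cells, which allows a share of up to 0.233%. Clusters 3, 6, 19 and 24 expressed PDX1, SOX9, ONECUT1 or NKX6-1, transcription factors of pancreatic progenitors, but had no such gene among their 10 leading genes and were compared by number. Clusters 3 and 19, led by ANGPT2, NTS, PRSS2 and LTB, held 43.5% and 10.9% of A951 and at most 0.105% of A952 or A953 each. Clusters 6 and 24, led by SFRP5, FXYD2, SLC4A4 and TM4SF1, held 7.71% and 1.44% of A952, 7.38% and 0.527% of A953, and 0 cells of A951. These 2 clusters also carried CFTR and SLC4A4, ion transporters of pancreatic ducts, and clusters 3 and 19 the hepatic markers APOA2 and SERPINA1 and the gastric markers CLDN18 and SOX2, with SERPINA1 among their leading genes.

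Endocrine-like clusters also split by hashtag. Cluster 1, led by the glucagon gene GCG with GC and PTPRS, held 23.0% of A952 and 4.72% of A953. Cluster 2, led by HOPX, RGS5 and the somatostatin gene SST, held 20.1% and 3.398%, and cluster 4, led by the zinc transporter gene SLC30A8 and LY6H, held 19.1% and 1.16%. In A951 the cells of clusters that took the endocrine name lay mainly in cluster 18, led by CCK, GHRL and NPY. Cluster 18 held 14.0% of that hashtag (12.1 to 15.98) and 0 cells of the others. Its 10 leading genes held APOA2, a hepatic marker, and 0 genes of the endocrine marker list, so it was compared by number. Over the whole cluster 6 endocrine markers were counted, beside NEUROG3, PAX4 and NKX2-2 of the endocrine progenitor list. Clusters 8 and 12 took the endocrine progenitor name. Cluster 12, led by NEUROG3, the transcription factor that starts endocrine differentiation, held 21.1% of A951 and 1 cell of A953. The endocrine markers CHGA, NEUROD1, INSM1 and SCG2 were counted in it as well. Cluster 8, compared by number, had the endocrine markers CHGA and CHGB but 0 endocrine progenitor markers among its 10 leading genes, beside TPH1, DDC and FEV, and held 14.4% of A952 and 1.13% of A953. Clusters 13 and 27, which carried 3 ductal markers each but had 0 of them among their 10 leading genes, were compared by number. Together they held 7.56% of A953, 0.495% of A952 and 0 cells of A951. No cluster took its name from the neural or Schwann, intestinal, gastric, smooth muscle or pericyte, or mesothelial markers. Proliferation markers passed the naming limits in full in clusters 7, 14, 17, 19 and 24.

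**Figure D1:**
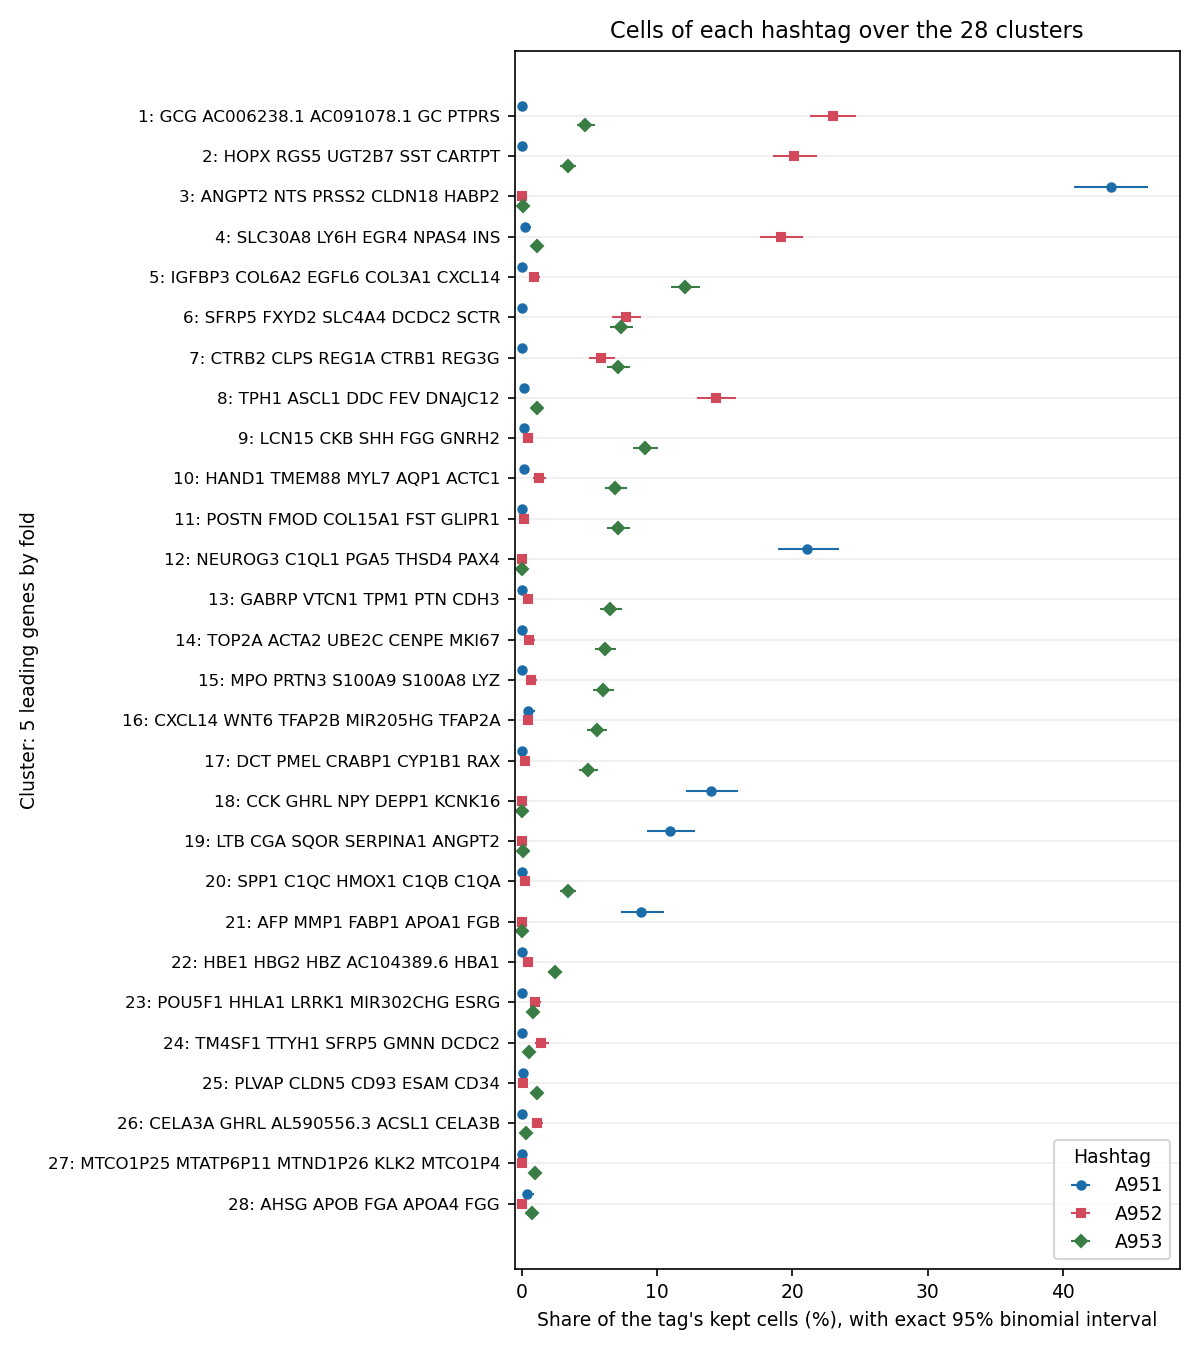
Share of the kept cells of each hashtag (percent, horizontal axis) in each of the 28 clusters (vertical axis, with the 5 leading genes), as points with exact 95% binomial intervals. Cluster 3 holds 43.5% of A951, cluster 1 holds 23.0% of A952, and cluster 7, the acinar-like cells, holds 5.90% of A952 and 7.14% of A953.

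The first comparison set acinar-like cells against the clusters with pancreatic progenitor markers, since the series' title names acinar development. Genes of digestive juice outside the naming markers were far higher in acinar-like cells. CTRC, which encodes chymotrypsin C (GRCh38 chromosome 1, 15438439 to 15449242), stood at 901 CPM against 3.11 CPM, a log2 ratio of 8.17 (7.94 to 8.43). REG1A, a secreted lectin of acinar cells (chromosome 2, 79120362 to 79123419), stood at 4168 against 4.75 CPM, a log2 ratio of 9.77 (9.58 to 9.98). RBPJL and PTF1A, which together form the transcription factor complex of acinar cells, were higher by log2 ratios of 5.57 (5.35 to 5.82) and 2.99 (2.82 to 3.15). Of the further ductal genes 9 of 13 were lower, of the WNT list 6 of 16 and of the Hippo and YAP list 5 of 10, and several lists depended on the reference clusters. Over the report lists, 46 of 188 measured genes were higher and 35 lower, and over all genes 1115 of 21379 were higher and 2573 lower. The comparison held 414 acinar-like cells with 12912360 counts and 1233 cells of the progenitor-marker clusters with 44624272 counts. Of the latter cells, 702 came from A951, which had no acinar-like cells, so the medians of most lists within A952 and A953 follow, in that order, with the values of some named genes that were under 2-fold within either.

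Of 13 measured further digestive enzymes, 10 were higher and 1, the amylase gene AMY2B, was lower, with a median log2 ratio of 4.02 that exceeded all random lists. Within A952 and A953 the medians were 4.54 and 5.31. Acinar-like cells were named from other enzyme genes, so the high ranks of this and the other acinar lists are no independent check of the name. PNLIPRP2, a pancreatic lipase relative, stood at 57.3 against 0.247 CPM (log2 ratio 7.80, 7.01 to 8.87), and CELA2B, an elastase, had 90 counts against 0. PRSS2, trypsinogen 2, was 1.02 higher on the log2 scale over all hashtags but 6.59 and 7.88 higher within A952 and A953, and clusters 3 and 19 of A951 carried it too, as did clusters 12, 18 and 21 of A951 at 884, 242 and 2366 CPM. Of 12 other acinar secretory and granule proteins, 10 were higher and 0 lower (median 4.25, above all random lists; 2.46 and 3.23 within A952 and A953). Besides REG1A, these included SYCN, a zymogen granule protein, at 225 against 1.03 CPM (log2 ratio 7.76) and CUZD1 at 43 counts against 0 (6.73 within A953). Within A952 the 0.76 of CUZD1 is what the prior and the totals give without a count on either side. CTRC and REG1A stood at 1.34 and 2.41 CPM in immune, erythroid and endothelial cells, a level to set beside their low values in the progenitor-marker clusters.

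Among 7 acinar transcription factors, PTF1A, RBPJL, NR5A2 and XBP1 were higher and NR0B2 was lower, at a log2 ratio of −1.38 (median 1.10, above all random lists; 1.57 and 2.36 within A952 and A953). NR5A2 was 1.29 higher, and 1.10 and 0.58 within A952 and A953. RBPJL (chromosome 20, 45306851 to 45317824) was 4.23 and 4.40 higher on the log2 scale within A952 and A953, and PTF1A (chromosome 10, 23192327 to 23194252) 3.89 and 3.24. Of 16 genes of the endoplasmic reticulum and protein secretion, DNAJB9, HERPUD1, ERN1 and SEL1L, all of the unfolded protein response or of protein degradation at that membrane, were higher and 0 were lower (median 0.47, above all random lists; 0.42 and 0.84 within A952 and A953). DNAJB9 had a log2 ratio of 1.99, ERN1 of 1.52 (0.48 and 1.18 within A952 and A953) and SEL1L of 1.41. Of 9 secretagogue receptor and exocytosis genes, CCKAR, CHRM3 and SYT1 were higher and STX3 lower (−1.59, but −0.33 within A952), with a median of 0.18 at percentile 96.6, and 0.95 and 0.55 within A952 and A953. The cholecystokinin receptor gene CCKAR had a log2 ratio of 2.60 (2.30 to 2.91) and the muscarinic receptor gene CHRM3 of 2.29 (1.96 to 2.64), at 19.4 and 13.9 CPM in acinar-like cells, and SYT1 had one of 2.11.

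Of 16 Notch genes, HEYL was higher, at 190 against 12.5 CPM (log2 ratio 3.93, 3.79 to 4.06), and HES4 (−1.41) and HEY1 (−1.17, but −0.41 within A952) were lower, all of them transcriptional targets of Notch. The Notch list had a median of −0.23 at percentile 36.3, with medians of 0.11 within A952 and −0.57 within A953. Of 16 WNT genes, 0 were higher and 6 were lower. Among the latter were FZD5 (−2.68), a receptor, SFRP1 (−3.03, but −0.90 within A953), a secreted inhibitor, and LEF1 (−4.22), a nuclear effector with 0.0774 against 2.15 CPM. LEF1 rested on 1 count in acinar-like cells against 96, with an interval from −10.1 to −2.28. The WNT median was −0.45 at percentile 4.66, and −1.47 and −1.09 within A952 and A953. Of 10 Hippo and YAP genes, 0 were higher and 5 were lower, with WWTR1 at −2.35, ANKRD1 at −1.62 and CCN2 at −1.31 (median −0.99, below all random lists; −1.07 and −1.52 within A952 and A953). Of 11 FGF and ERK genes, 0 were higher and 4 were lower, with FGFR2 at −2.01, DUSP6 at −1.87 and SPRY2 at −1.81 (median −0.86, percentile 0.14; −0.98 and −0.55 within A952 and A953). DUSP6 differed by only −0.10 and −1.21 and SPRY2 by −0.98 and −0.76 within A952 and A953.

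Of 13 further ductal genes, 0 were higher and 9 lower (median −1.64, below all random lists), with medians of −1.56 and −1.58 within A952 and A953. BICC1, an RNA-binding protein of duct epithelia, stood at 5.65 against 87.2 CPM (log2 ratio −3.94, −4.30 to −3.61), and CA2 and CLDN1 had log2 ratios of −2.93 and −2.77. Within A952 and A953, CA2 differed by only −1.17 and −0.77 and CLDN1 by −1.64 and −2.43. Of 10 further endocrine genes, ABCC8 was higher (1.37) and TTR (−4.02) and ISL1 (−1.58) were lower (median −0.18, percentile 49.0; 0.62 and −0.75 within A952 and A953). Within A952 and A953, ABCC8 differed by 2.16 and 0.38, TTR by −1.64 and −1.55 and ISL1 by −0.60 and −2.49. Of 9 fetal genes, DLK1, an imprinted gene of fetal tissues, was higher at 20312 against 7490 CPM (1.44), and AFP, the fetal serum protein gene, was lower at 162 against 3589 CPM (−4.47). AFP differed by −0.99 within A952 and −0.08 within A953, and its high level lay in clusters 3 and 19. The fetal list had a median of −0.16 at percentile 29.3, and 0.08 and −0.12 within A952 and A953. Of 12 replication and mitosis genes, TYMS (1.20), CDK1, CCNA2 (1.14) and RRM2 (1.65) were higher and 0 lower (median 0.61, percentile 99.99; 0.56 and 1.05 within A952 and A953). Within A952 alone, TYMS differed by 0.93, CDK1 by 0.21 and CCNA2 by 0.47.

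Of 10 genes of the stress response to cell dissociation, 7 were higher and 0 lower (median 1.54, above all random lists; 1.19 and 0.31 within A952 and A953), with JUNB at 2.60, EGR1 at 1.89 and FOS at 1.82. Within A953, EGR1 and FOS differed by 0.84 and 0.75. Against clusters 6 and 24, which came from the same hashtags as the acinar-like cells, JUNB was higher by 1.55 as 1 of 10, and the list's median of 0.56 still stood at percentile 99.88 of the random lists, with 1.18 and 0.29 within A952 and A953. Of 10 hypoxia and glycolysis genes, LDHA was higher (1.44, but 0.74 within A953) and VEGFA lower (−1.23), with a median of 0.08 at percentile 95, and 0.60 and 0.03 within A952 and A953. Of 7 MHC class I genes 0 differed 2-fold (median −0.19, percentile 37.3), and of 7 measured niche ligands WNT2B (−3.54) and WNT2 (−1.33) were lower (median −0.14, percentile 73.3). WNT2 rested on few counts, with an interval from −3.89 to 0.15 and −0.83 within A952. Outside all lists the largest ratios belonged to FO681525.1, at 166 against 0.134 CPM (log2 ratio 10.16), to OPN4, the melanopsin gene, at 22.3 against 0.0224 CPM, and to SKOR1, AC092957.1 and MAG, which had 0 counts in the progenitor-marker clusters. On the lower side were SLC26A3, an intestinal chloride exchanger (−8.09, but −0.83 and −0.45 within A952 and A953), and C9orf24, CER1, INHBB and TFF1 (−0.83 within A952), with 0 counts in acinar-like cells. The values of SLC26A3 and TFF1 within these hashtags rest on a few counts at most and on the prior. Measured genes had a median log2 ratio of −0.20, and TMM factors moved that median by 0.15, CPM without enzyme, mitochondrial and ribosomal protein genes by 0.13, and leaving out A953 by 0.14.

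Because clusters 6 and 24 shared the hashtags of the acinar-like cells, they were also taken alone as the reference, a choice made after the hashtags of the clusters had been seen. Of 183 measured genes of the report lists, 52 were then higher in acinar-like cells and 43 lower. All further digestive enzymes measured except AMY2B were higher, 12 of 13, with PRSS2 at 3570 against 12.7 CPM (log2 ratio 8.13, 7.94 to 8.33) and CEL, a lipase, at 443 against 25.6 CPM (4.11). GATA4, a transcription factor of early pancreas, was higher by 2.17 in this comparison, while NR5A2 differed by 0.74. Of the WNT list, 9 of 16 genes were lower and WNT5A was higher (median −1.22, below all random lists), and of the Hippo and YAP list 7 of 10 were lower, with WWTR1 at −3.24 and YAP1 at −1.28. The ductal genes CFTR, PKHD1 and SCTR differed by −3.64, −2.91 and −1.95. Of the FGF and ERK list FGFR1 and SPRY4 were higher and FGFR2, FGFR3 and FGFR4 lower, with DUSP6 and SPRY2 neither (median −0.72, percentile 0.48). DLK1 was higher by 1.49, AFP differed by 0.09 and TTR by −1.56. Of the replication list 6 of 12 genes were higher, with RRM2 at 2.25. Against clusters 3 and 19 alone, 56 of 184 measured genes were higher and 37 lower. Here no hashtag held 20 cells of both sides, so direction within a hashtag was not checked and cluster cannot be separated from hashtag. Dissociation stress genes were higher in 8 of 10 cases (median 2.74, above all random lists). The WNT list then had 4 genes higher, AXIN2 (1.08), ZNRF3 (1.72), NKD1 (1.60) and DKK1 (4.98), and 4 lower, with a median of 0.24 at percentile 98.8. Of the Hippo and YAP list CCN1 was higher and 3 genes lower (median −0.19, percentile 44.3), and of the ductal list CLDN10 (4.53), SCTR (1.79), PKHD1 (1.60) and ELF3 (1.31) were higher and 7 lower (median −1.05, percentile 0.01).

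Acinar-like cells were also set against clusters 13 and 27, which together held 299 cells, 287 of them from A953. Of 182 measured report-list genes, 85 were higher in acinar-like cells and 38 lower. Of the dissociation stress genes 7 of 10 were higher (median 1.26, above all random lists). Of the further ductal genes, 6 of 13 were higher, among them SCTR (4.01), and 5 lower, among them CA2 (−4.05) and ANXA3 (−3.44), with a median of 0.56 at percentile 99.3. With more of these genes higher than lower in acinar-like cells, clusters 13 and 27 are not shown to be duct cells. Further digestive enzymes were higher in 12 of 13 cases, with PNLIPRP2 at 8.37 and CEL at 8.15, and all 7 acinar transcription factors were higher, with RBPJL at 7.30, PTF1A at 6.46 and GATA4 at 5.97. HEYL was higher by 7.99, FGFR4 by 4.35 and DLK1 by 5.80. Lower were SFRP1 (−6.17), ISL1 (−5.88), RSPO3 (−5.15) and SLC2A1, a glucose transporter gene, at 41.7 against 1911 CPM (−5.52). Outside all lists LEFTY1 (9.85), CXCL1, SPRR2F, CDH23 and AL590556.3 led the higher side, and TFAP2B (−12.56) and 4 mitochondrial pseudogenes the lower side. Such pseudogenes held 17.5% of the counts of cluster 27 and at most 0.386% in any other cluster, cluster 13 included. WNT4 (−4.15), JAG2 (−4.19) and LIN28B (−1.52) changed direction without A953, which left 12 cells of the 2 clusters.

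**Figure D2:**
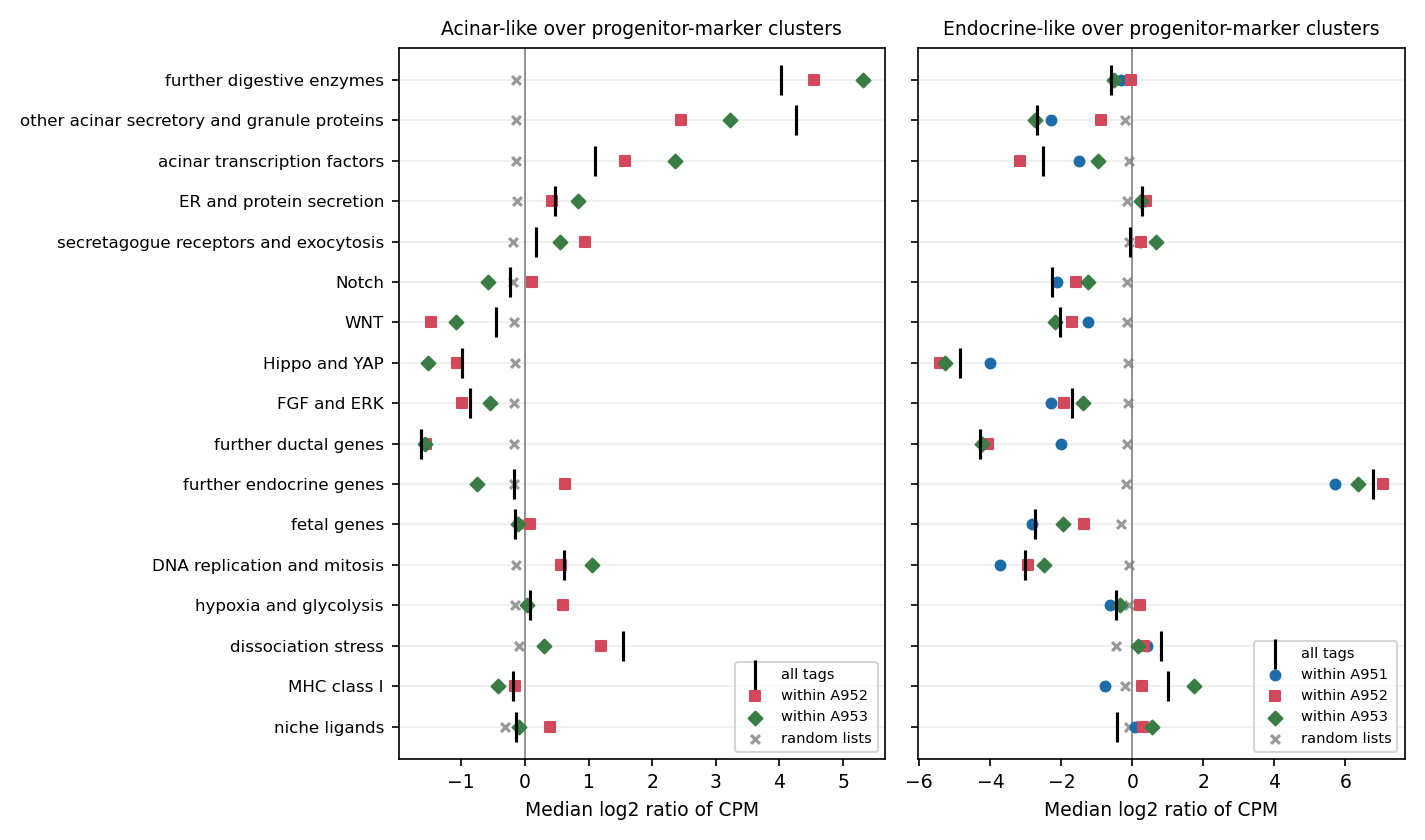
Median log2 ratio of CPM (horizontal axis) of each report list (vertical axis) for acinar-like cells (left) and endocrine-like cells (right) over the clusters with progenitor markers. Black bars give all hashtags, coloured points single hashtags and grey crosses the median of random lists. Digestive enzymes have a median of 4.02 on the left and further endocrine genes one of 6.77 on the right.

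The progenitor-marker clusters themselves differed by hashtag. Set against clusters 3 and 19 (711 cells, 702 of them from A951), clusters 6 and 24 (522 cells of A952 and A953) had 49 of 182 measured report-list genes higher and 35 lower. Cluster and hashtag cannot be separated here. Dissociation stress genes had the largest median of any list, 2.03, with 7 of 10 higher and 0 lower, among them FOS (1.98), JUNB (2.71) and EGR1 (2.22). Of the WNT genes 10 of 16 were higher and 2 lower (median 1.65, above all random lists), including the targets NKD1 (3.20), LEF1 (2.23), AXIN2 (2.12) and LGR5 (1.32). Of 10 Hippo and YAP genes 6 were higher, including CCN2 (2.33), CCN1 (2.02) and WWTR1 (1.98). BICC1, PKHD1 and SCTR of the ductal list were higher by 4.81, 4.51 and 3.74. Lower were PRSS2, at 12.7 against 2858 CPM (−7.81, −8.01 to −7.62), RNASE1, at 5.15 against 303 CPM (−5.87), and AFP, at 152 against 5761 CPM (−5.24).

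Endocrine-like cells were compared with the same progenitor-marker clusters as a second lineage of pancreas; whether they arose from these clusters was not tested. Of 11 further endocrine genes, 10 were higher, all but MAFA (median 6.77, above all random lists). The cells were named from other endocrine genes, so this rank is no independent check of the name. The transcription factor gene PAX6 stood at 354 against 2.78 CPM (log2 ratio 6.99, 6.74 to 7.26), SLC30A8 at 236 against 1.70 CPM (7.11, 6.79 to 7.46) and the potassium channel gene KCNK16 at 484 against 3.70 CPM (7.03, 6.81 to 7.26). All 12 replication and mitosis genes were lower (median −3.01), as were 9 of 10 Hippo and YAP genes (median −4.86) and 12 of 13 ductal genes (median −4.28), each list below all random lists, with ductal medians of −2.00, −4.06 and −4.23 within A951, A952 and A953. Over the report lists, 29 of 187 measured genes were higher and 80 lower, and over all genes 2659 of 24141 were higher and 3255 lower. The comparison held 2044 cells of clusters 1, 2, 4 and 18, all with endocrine markers counted and called endocrine-like here. Clusters 8 and 12 also had endocrine markers counted, but took the endocrine progenitor name and were left out. Of the 2044 cells, 183 came from A951, 1509 from A952 and 352 from A953. Of the 183, 180 were in cluster 18, so values within A951 rest on a cluster compared by number. Its leading genes held no gene of the endocrine marker list, but did hold GHRL and KCNK16. Without cluster 18, 31 report-list genes were higher and 83 lower. PAX6, SLC30A8 and KCNK16 stood at 2.53, 0.989 and 2.61 CPM in immune, erythroid and endothelial cells, so their values in the progenitor-marker clusters were within 2-fold of that background. MAFA, a transcription factor of mature beta cells, was at 0.756 CPM in A952 and 2.23 CPM in A953, with 0 counts in A951.

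CDK1, which drives entry into mitosis, stood at 0.905 against 33.4 CPM (log2 ratio −5.20), and TYMS and CCNB1 had log2 ratios of −4.55 and −4.45. The YAP targets CCN1 and CCN2 stood at 1.64 against 174 CPM (−6.72, −7.02 to −6.45) and 1.78 against 130 CPM (−6.18), and WWTR1 at 1.70 against 95.2 CPM (−5.80). In the ductal list, SCTR, PKHD1 and ANXA2 had log2 ratios of −5.07, −5.05 and −4.94. Of 16 Notch genes, JAG2, DLL4 and MFNG were higher and 8 were lower, including NOTCH1 (−4.99), JAG1 (−4.86) and NRARP (−3.53), with a median of −2.27 below all random lists. Of 16 WNT genes, WNT4 and SFRP1 were higher and 7 lower, including LEF1 (−4.23), FZD7 (−4.08) and FZD5 (−3.72), with a median of −2.04 below all random lists. Within A951, MFNG and WNT4 differed by only 0.24 and 0.19. Of 11 FGF and ERK genes 6 were lower, among them ETV4 (−4.63), FGFR3 (−3.81) and SPRY2 (−2.50), with a median of −1.71 at percentile 0.02. Of 8 measured fetal genes 5 were lower, with IGF2 at 141 against 8287 CPM (−5.88), DLK1 at 195 against 7490 CPM (−5.26) and HMGA2 at −4.91 (median −2.74, below all random lists).

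Of 7 acinar transcription factors in the endocrine comparison, NR5A2 (−4.88), PTF1A (−4.68), RBPJL (−3.00) and NR0B2 were lower (median −2.52, percentile 0.01; −1.50, −3.17 and −0.96 within A951, A952 and A953). Of 11 other secretory proteins, 7 were lower, among them ERP27 (−6.16), GP2 (−4.38) and GATM (−3.77), and TMED6 was higher (1.64, but 0.54 within A952), with a median of −2.68 below all random lists, and −2.29, −0.88 and −2.74 within A951, A952 and A953. Of 12 further digestive enzymes, CEL (−2.92) and RNASE1 (−5.88) were lower and PRSS3 was higher, at 53.3 against 5.29 CPM (3.33, 3.14 to 3.53), with a median of −0.60 at percentile 7.08, and −0.31, −0.05 and −0.52 within A951, A952 and A953. Within A951, A952 and A953, RNASE1 differed by −5.53, −0.92 and −1.25 and CEL by −0.54, −1.77 and −5.01. Of 16 genes of protein secretion, PDIA4 (−2.67) and PDIA6 (−1.02, and between −0.95 and −0.73 within each hashtag) were lower (median 0.28, percentile 98.4). Of 9 exocytosis genes, CHRM3 (2.02, but 0.57 within A951) and SYT1 (4.08), a calcium sensor of secretory vesicles, were higher, and CCKAR (−5.54), RAB27B (−3.41) and VAMP8 were lower (median −0.07, percentile 51.7). The median of these exocytosis genes was 0.21, 0.25 and 0.66 within A951, A952 and A953.

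Of 10 dissociation stress genes, FOS (1.68), FOSB, JUNB (3.58) and EGR1 (1.67) were higher (median 0.79, percentile 99.96), with medians of 0.42, 0.33 and 0.16 within A951, A952 and A953. FOSB differed by 0.46, 0.79 and 0.08 within them, and FOS and EGR1 by 0.72 and 0.75 within A953. HLA-E of the MHC class I list was higher (1.84), and the list's median of 1.00 (percentile 99.6) was −0.78 within A951, 0.28 within A952 and 1.72 within A953. Of 10 hypoxia and glycolysis genes, BNIP3 was higher (1.25) and ENO1 lower (−1.04, but −0.64 and −0.78 within A951 and A953), with a median of −0.45 at percentile 9.10, and −0.64, 0.22 and −0.34 within A951, A952 and A953. Of 8 measured niche ligands, FGF7, RSPO3 (3.51) and GREM1 were higher and WNT2B (−3.40, but −0.11 within A951) and WNT2 (−2.23, but −0.29 within A952) lower, with a median of −0.45 at percentile 15.8, but 0.07, 0.31 and 0.57 within A951, A952 and A953. FGF7 differed by 0.92 within A952 and GREM1 by 0.68 within A951. Outside all lists, SUCNR1, a succinate receptor gene, stood at 45.5 against 0.0672 CPM (9.18, 7.85 to 11.68) and TAC1, the gene of substance P, at 21.0 against 0.0224 CPM, while C11orf87, SYNDIG1L and LINC00588 had 0 counts in the progenitor-marker clusters. Within A951 the 0.22 of TAC1 is what the prior and the totals give for a count in the progenitor-marker clusters only. Its direction there therefore did not rest on counts in endocrine-like cells. LTB was lower, at 0.322 against 147 CPM (−8.80), and PSAPL1, TNNI2, TCN1 and CLDN2 had 0 counts in endocrine-like cells. Measured genes had a median log2 ratio of −0.11, which TMM factors moved by 0.12 and CPM without hormone, CHGA, TTR, mitochondrial and ribosomal protein genes by 0.20. Hormone RNA was also found in cells of other lineages, with GCG at 198 CPM, INS at 138 CPM and CHGA at 250 CPM in immune, erythroid and endothelial cells and 219, 156 and 278 CPM in acinar-like cells.

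Within the acinar-like cells, A953 held more enzyme RNA than A952. The further digestive enzymes summed to 7167 CPM in A953 (7111 to 7223) and 2148 CPM in A952 (2103 to 2193). The secretory granule protein gene GP2 stood at 274 CPM (263 to 285) in A953 and 23.7 CPM (19.2 to 28.9) in A952, PRSS2 at 4759 and 978 CPM, CEL at 589 and 124 CPM, and the colipase gene CLPS at 18545 and 7771 CPM. CTRB2, chymotrypsinogen, stood closer, at 13815 and 11818 CPM. CPB1, a carboxypeptidase, went the other way, at 61.1 CPM (56.1 to 66.5) in A953 and 171 CPM (158 to 184) in A952. RBPJL stood at 209 and 91.4 CPM, whereas PTF1A stood at 71.0 (65.6 to 76.8) and 87.5 CPM (78.6 to 97.1) and DLK1 at 16783 and 28012 CPM. PNLIP, the main lipase, was low in both, at 13.1 and 2.46 CPM, and AMY2A, pancreatic amylase, had 0 counts in both, which allows at most 0.417 and 0.909 CPM. The proliferation marker MKI67 stood at 189 and 135 CPM. Each hashtag was measured once, so these differences have no replicate check.

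**Figure D3:**
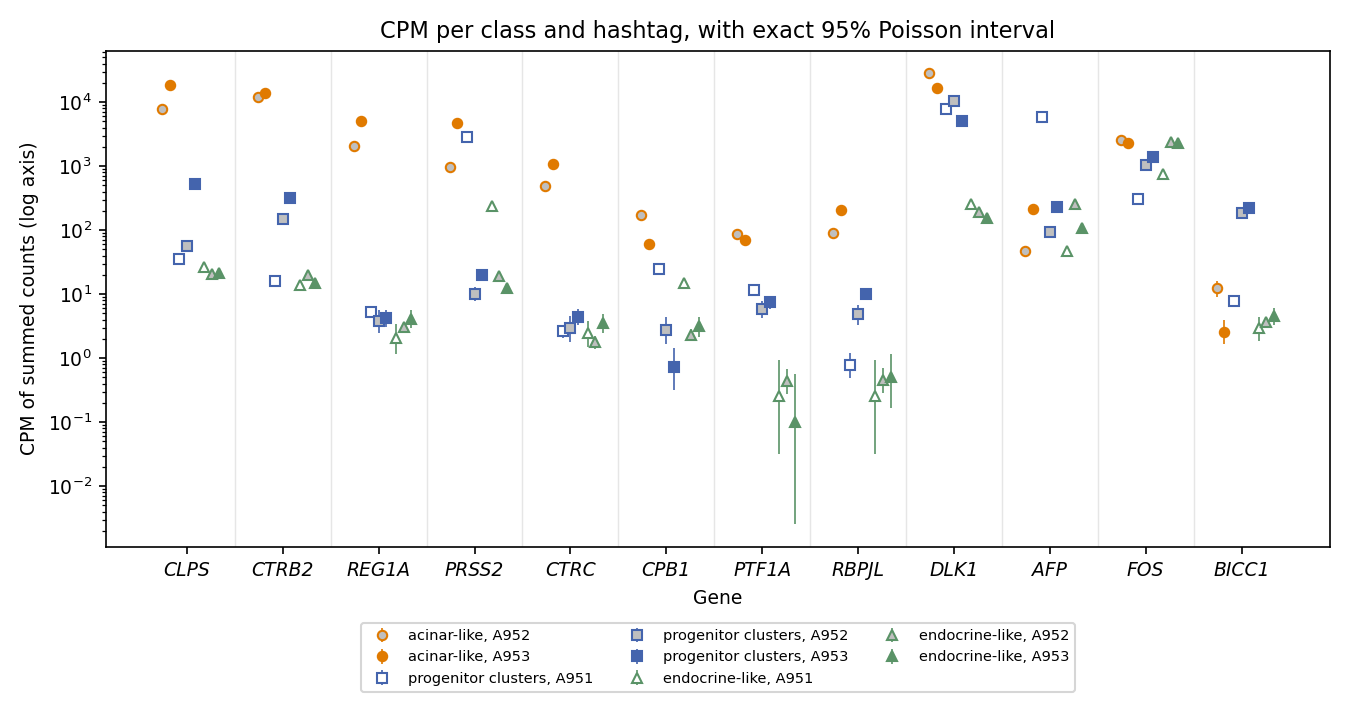
CPM of summed counts (vertical log axis) of 12 genes (horizontal axis) in acinar-like cells (circles), clusters with progenitor markers (squares) and endocrine-like cells (triangles) of each hashtag, with exact 95% Poisson intervals; points with 0 counts are not drawn. PRSS2 stands at 2898 CPM in the progenitor-marker clusters of A951 and at 10.1 and 20.1 CPM in those of A952 and A953, and BICC1 at 186 and 223 CPM in the latter.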

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

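No explanation was tested in this part, so it holds no test chosen after the results were seen. Besides the 3 hashtags that name cells, the hashtag library listed 8 tags that name no cell and that no comparison uses. Each had more reads than the 3 that a count of 0 allows. Tag A954 had 6575 reads, spread over 753 barcodes with at most 65 in 1 barcode, and 65.6% of them lay in cells of the matrix. Tag A963 had 141 reads, A955 had 73, A962 had 36, A436 had 32, A961 had 17, A965 had 16 and A964 had 15. The hashtags A951, A952 and A953 held 99.99% of all 56496674 reads.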

How the results depend on the processing

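The automatic doublet threshold, the settings without cluster 18, the share of the endocrine and endocrine progenitor clusters together, and the endocrine comparison at resolution 0.5, with the report lists in the clustering, with TMM factors and without hormone genes were chosen after the results were seen. The other settings had been laid out before. The share of clusters that took the endocrine name from their markers, 27.2% of kept cells, was the least stable of the shares checked. It leaves out clusters 8 and 12, which had endocrine markers counted but took the endocrine progenitor name. It was 24.8% without cluster 18, which is compared by number, and, with names given anew, 16.5% with at least 200 genes per cell, 18.8% with at least 1000, 16.6% at resolution 0.5, 17.5% with the automatic threshold and 25.7% with scrublet's doublets kept. In those at 16.5 to 18.8%, between 92.5% and 100% of the 617 cells of cluster 2, led by HOPX and SST, took the endocrine progenitor name. The share of both classes together stayed between 35.2% and 36.7% under all 7 settings, against 36.1%. The acinar-like share, 5.51%, was 6.07% with the report lists in the clustering and 6.19% at resolution 2.0, and 5.50 to 5.53% under the other 5 settings; the cause was not tested. The progenitor-marker share stayed within its interval, at 15.8 to 16.9%. Assigning cells by at least 75% of hashtag reads gave 16.1%, 31.8% and 49.99% for A951, A952 and A953.

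Counts of report-list genes stayed within 1.5 times with 1 exception. In the acinar comparison 43 to 51 genes were higher and 32 to 43 lower, leaving out each hashtag included, and in the endocrine comparison 27 to 38 and 78 to 87. Against clusters 13 and 27, 76 to 88 were higher and 36 to 42 lower, but 19 lower without A953, which left 12 cells of these clusters. Of 1597 ratios of named genes under the other settings, 1101 stayed inside their interval and 493 left it. The 3 that reversed, all against clusters 13 and 27 without A953, were JAG2, WNT4 and LIN28B, at 0.40, 0.14 and 3.61 without A953 and −4.66, −8.25 and −2.00 without A952; the cause was not tested. Thinned to 10000 counts per cell, which kept 396 of 414 acinar-like cells, the summed digestive enzymes of A952 were 1994 CPM, below their interval for a cause not tested, and those of A953 were 7149 CPM. Depth limits rare genes: 0 counts in acinar-like cells allowed up to 0.909 CPM in A952 and 0.417 CPM in A953.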

Other observations

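Many kept cells belonged to no pancreatic lineage, and most of these carried A953. Mesenchymal-like clusters 5 and 11 held 12.1% and 7.14% of A953. Clusters 10 and 14, with mesenchymal markers counted but more markers of another class among their leading genes, held 6.93% and 6.14%. Cluster 5 was led by IGFBP3 and matrix genes, with COL3A1 at 23890 CPM and COL1A1 at 20418 CPM, and cluster 10 by HAND1, MYL7 and ACTC1, genes of early heart and lateral mesoderm. Cluster 15, 6.03% of A953, was led by MPO (9184 CPM) and PRTN3 (7352 CPM), granule enzymes of immature myeloid cells. Cluster 20, compared by number, 3.398% of A953, was led by SPP1 and the complement genes C1QA, C1QB and C1QC of macrophages. Erythroid-like cells numbered 12 in A952 and 93 in A953 (2.45%, 1.98 to 2.99). Their globins were embryonic and fetal, with HBE1 at 42259 CPM, HBZ at 37325 CPM and HBG2 at 33358 CPM, against 19.5 CPM for the adult gene HBB. Endothelial-like cells, led by PLVAP and CLDN5, made up 1.13% of A953 and 0.0825% of A952.

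Epithelial and other lineages were present as well. Hepatic-like cluster 21 held 8.84% of A951 and 0 cells of the others, with AFP at 54005 CPM and APOA1 at 29946 CPM. The intestinal markers CDX2 and VIL1 and the ductal markers CFTR and TSPAN8 were also counted in it. FABP1 and TFF1 were among its leading genes. Cluster 28, led by AHSG and APOB, held 30 cells of A953. Pluripotent-like cells numbered 24 in A952 (0.990%, 0.635 to 1.47) and 31 in A953 (0.817%, 0.556 to 1.16), with POU5F1 at 1715 CPM and NANOG at 112 CPM, against 0.929 and 6.58 CPM in acinar-like cells. Unnamed cluster 17, 4.87% of A953, was led by DCT and PMEL, genes of pigment cells, and RAX, SIX3 and SIX6 of the eye field. Unnamed cluster 9, 9.14% of A953, was led by LCN15, CKB and SHH. Unnamed cluster 16, 5.56% of A953, was led by CXCL14, WNT6 and TFAP2B, and cluster 13, 6.56% of A953, with some ductal markers but compared by number, was led by GABRP and VTCN1.

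All tests of the patterns that follow were chosen after the results were seen, so what they leave open is a hypothesis, and no biological explanation could be set against the hashtags, whose conditions are unknown. The kidney tubule list was written after the leading genes of cluster 27 had been seen, and CALB1, which was among them, was left out. Its scoring was changed once, from a ratio with a prior to a plain CPM ratio, because SLC12A1 with 0 counts in the cluster had counted as higher; the prior would give 18 genes instead of 17.

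Cells of cluster 26 (39 cells, 27 from A952 and 12 from A953) expressed the ghrelin gene GHRL at 74840 CPM together with the elastase gene CELA3A (chromosome 1, 22001656 to 22012539) at 12570 CPM, against 205 CPM in acinar-like cells, and 26 of them (66.7%) had CELA3A counts. RNA of acinar-like cells would bring their most abundant genes, but CLPS and CTRB2 together gave 0.003884 counts per CELA3A count, against 138.3 in acinar-like cells. A fixed split of reads with CELA3B would keep the ratio of both genes, which was 18.78 here against 1.015 there. AL590556.3, which overlaps CELA3A on the same strand, stood at 2852 CPM, and reads of its transcript were not told apart from those of CELA3A. The cells may carry elastase RNA of their own, a hypothesis found and tested on the same cells.

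Cluster 27 (39 cells, 38 from A953) was led by nuclear copies of mitochondrial genes, with 17.5% of its counts on 126 such pseudogenes, against 0.0989 to 0.386% in the other clusters. Misplaced human mitochondrial reads would follow the human genes, but MTCO1P25 (chromosome 7, 69331835 to 69333633) had 4.076 counts per MT-CO1 count, against at most 0.002754 elsewhere. The mitochondrial genes held 3.752% of counts against a median of 6.401%, but with the pseudogenes added the share was 21.2%, against at most 9.54% elsewhere, so this test cannot exclude damaged cells, and the cluster also had the lowest median count, 10633. Of 21 measured kidney tubule genes, 17 (80.95%) were at least 2-fold higher than in all other cells, among them SLC12A3 (1287 CPM), PVALB (1385 CPM) and SLC34A1 (924 CPM), while CUBN, SLC12A1 and CLDN16 had 0 counts. In the other cells 9 of the 21 exceeded 1 CPM, and 0 were in another list. Of the 12 under 1 CPM there, 11 were at least 2-fold higher, but few counts can suffice for that, as the 2 counts of SCNN1G did. The share of all genes that would pass this limit was not computed. The cells may be kidney tubule cells, possibly of the host, and damage stays open as well; their species was not tested and no mouse genome was used here.

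Clusters 3 and 19, almost all from A951, carried PRSS2 (chromosome 7, 142760398 to 142774564) at 2858 CPM in 86.6% of their cells, near the 3570 CPM of acinar-like cells, although A951 held 0 acinar-like cells. RNA of acinar-like cells would bring CLPS and CTRB2, but these gave 0.01795 counts per PRSS2 count, against 7.939 in acinar-like cells. A fixed split of reads with the related gene PRSS1 would keep the ratio of PRSS2 to PRSS1, which was 5.93 against 2.366. PRSS2 was not limited to these clusters, since it stood at 884, 242 and 2366 CPM in clusters 12, 18 and 21 of A951, against 12.7 CPM in clusters 6 and 24 and 8.70 CPM in immune, erythroid and endothelial cells, mostly of other hashtags. The cells may express PRSS2 themselves, but this hypothesis rests on 1 hashtag, and RNA passed among the cells of A951 before pooling was not tested and stays open.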
